A study of Macaca fascicularis with 56 samples.

How the data were processed

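The deposited table held 54675 probe sets on 56 arrays. Its values were linear array intensities, made with MAS5 per the submitters' processing notes, which give no version or settings. MAS5 summarises the probes of a probe set into 1 signal and scales each array to a common mean. The mean left after trimming 2% of the values lay between 149.96 and 149.97 on every array, so the arrays had been scaled to one level by the submitters. Per the labels, blood of cynomolgus macaques was collected in PAXgene tubes, total RNA was extracted with the matching kit, and biotinylated cDNA was prepared from 50 ng with a NuGEN whole blood kit. The probe names belong to a human genome array, so macaque RNA was read with probes designed on human sequence. Levels were therefore not compared between genes, only between groups for one gene.

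The following choices were made before the data were examined. The values were put on the log2 scale without a further normalization between arrays. A probe set was kept if it lay above the median of all probe sets of that array on at least 4 of the 56 arrays, which left 38767. The array medians ran from 12.9 to 23.5 on the linear scale. Each gene was read by 1 probe set, the kept one with the highest mean over all arrays among those with exactly 1 gene symbol. Of the 54675 probe sets, 41097 had exactly 1 symbol, 1801 had several and 11777 had none in the probe table. Of the 16020 genes tested, 7881 had at least 2 kept probe sets of their own, 13561 carried a symbol of the macaque gene table and 245 had placeholder symbols, which are not named. The hemoglobin alpha and gamma genes had only probe sets shared between several symbols and were left out. The probe set of IL10, the gene of an anti-inflammatory cytokine, was above the array median on 3 arrays, reached at most 16.4, and was not tested.

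Genes were tested with limma 3.58.1 in R 4.3.3. One linear model over the 12 groups of arm and time was fitted to all 56 arrays, with a trend in the prior variance and robust moderation, and no block for the animal. Adjusted p values are Benjamini-Hochberg values within a comparison, and a gene was called at an adjusted p below 0.05. Tests were two-sided. The 29 comparisons were each later hour against 0 h within each arm, LR12 against both control arms, against the peptide control and against vehicle at each hour, the peptide control against vehicle at each hour, LR12 against both control arms on each animal's mean over 2, 4 and 8 h, and the difference between LR12 and both control arms in the change from 0 h. For both control arms together, the vehicle and peptide control means entered with equal weight. Errors given as SE are standard errors of limma, and levels are given as mean ± SD of log2 intensity. Fits against the same control animals share those animals' chance values.

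The labels number the animals, so the 4 arrays of an animal form a pairing. It was checked from the values left after removing the mean of each group. The 4 arrays of an animal correlated at a mean of 0.180 (from -0.00867 to 0.513), against -0.0294 to arrays of other animals, and 45 of the 56 arrays had their best match in an array of the same animal. The pairing was therefore taken as real, and the same tests with the animal as a block, with a consensus correlation of 0.221 from statmod 1.5.0, are given beside the results.

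The 30 gene lists were written before the data were examined. On inflammation they covered inflammatory cytokines, chemokines, NF-kB feedback and early response, anti-inflammatory mediators, the interferon response, TREM-1 and its adaptor pathway, endotoxin recognition, the inflammasome, and coagulation and fibrinolysis. Cell type lists covered mature neutrophils, neutrophil granules, monocytes, T cells, B cells, natural killer (NK) and cytotoxic cells, platelets, erythroid cells, eosinophils and basophils, and dendritic cells. The others were major histocompatibility complex (MHC) class II presentation, ribosomal proteins, oxidative phosphorylation, glycolysis and the hypoxia response, the proteasome, heat shock and the unfolded protein response, glucocorticoid-responsive genes, the cell cycle, leukocyte adhesion and migration, apoptosis, and array control genes. Each list was tested in each comparison with camera, which asks whether a list moved relative to all other genes, at its preset correlation of 0.01. The 30 lists were adjusted together within a comparison, which made 870 list tests. Camera with a correlation estimated from the data and fry, a rotation test that asks only whether the members moved, on balance, one way, were run beside it. Camera at the preset correlation called 382 of the 870, fry called 190, and camera with an estimated correlation called 20.

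Genes to name were chosen by a rule fixed before the data were examined. It took the 8 largest rises and 8 largest falls among called genes that changed in 1 direction in every animal of the arm, or whose values did not overlap between the arms compared. It added up to 4 called members of each list, the 5 genes with the smallest p where fewer than 5 were called, and in every comparison TREM1, TREML1, TYROBP, TNF, IL6, IL1B, IL10, CXCL8, CCL2, CD14 and TLR4. After the data were examined, the rule was extended unchanged to the time courses of the peptide control and LR12 arms and to LR12 against the peptide control.

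A batch was found in the values, since the labels give none. The array's control probe set for 18S ribosomal RNA fell into separate ranges, at most 6.80 on 33 arrays and at least 7.75 on 23 arrays (log2). The poly-A controls, which are added to the RNA before labelling, lay at 8.40 ± 0.50 (SD) on the 33 arrays and 10.79 ± 0.29 on the 23, and the log2 ratio of the 3' to the 5' actin probe set at 1.97 ± 0.37 and 1.23 ± 0.19. These are called the low-control and high-control arrays. With the groups in the model, 4656 genes differed between them, 1542 higher and 3114 lower on the high-control arrays. List medians differed too (high minus low): -0.46 for T cell, -0.48 for B cell and -0.44 for NK and cytotoxic cell markers, -0.45 for the cell cycle, -0.26 for MHC class II presentation, 0.30 for the interferon response and 0.26 for inflammatory cytokines and chemokines. The split is uneven over the groups. At 2 h, 1 of the 14 arrays was a high-control array, and at 4 h all 4 peptide control arrays were, as were 3 of 4 at 0 h. At 8 h only Y31305 of that arm had a low-control array, so the differences above can also hold those between animals. Results with this batch as a covariate or within a set of arrays, those without Y31303 and Y31305 together and the comparison of named changes with the 20th percentile were added after the data were examined.

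Every count and named gene was recomputed with quantile normalization, each array centred on its median, an offset added before the log, no filter and a stricter filter, all probe sets of a gene averaged, each probe set on its own, only the arrays compared, plainer moderation, a fold threshold and the animal as a block, and without each animal in turn.

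The method was tested on simulated data with only the spread and group sizes of these arrays. Of 100 genes changed by a log2 of 2, the fit recovered 60 each in the vehicle and peptide control arms at 2 h, 77 in the LR12 arm, 69 for LR12 against both control arms, 75 against the peptide control, and 58 for the peptide control against vehicle. Of 100 genes changed by a log2 of 1 it recovered 19 to 33 in these fits. False calls numbered 2 to 8, and camera called 0 of 30 unchanged lists. False calls under correlation between genes were therefore not tested.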

Results

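Gene expression was measured in whole blood of 14 cynomolgus macaques with human genome arrays, at 0, 2, 4 and 8 h. Per the labels, the series followed an endotoxin challenge and then treatment with LR12 or with LR12 in scrambled order. LR12 is a peptide derived from TREM-like transcript 1 (TREML1) that acts as a decoy for ligands of TREM-1, a receptor on neutrophils and monocytes that amplifies inflammatory signalling. The vehicle arm held 4 animals (Y31301 to Y31304), the peptide control arm 4 animals (Y31305 to Y31308), and the LR12 arm 6 animals (Y31309 to Y31314), each with 1 array per hour. The labels do not say whether the vehicle arm received endotoxin, at which point of the protocol hour 0 was sampled, or which doses were used. The number of arrays limits the precision.

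The arrays shared one scaled mean, but their middle did not stay level. The median value of an array was 18.4 ± 2.0 (SD, 14 arrays) at 0 h, 18.0 ± 0.68 at 2 h, 15.5 ± 2.1 at 4 h and 15.9 ± 1.8 at 8 h. The median log2 change over all 16020 genes was therefore -0.18, -0.29 and -0.27 in the LR12 arm at 2, 4 and 8 h, -0.04, -0.26 and -0.11 in the peptide control arm, and 0.03, -0.15 and -0.06 in the vehicle arm. With each array centred on its median, it was -0.02, 0.02 and -0.003 in the LR12 arm. Changes of gene lists are therefore given relative to the median of all genes, and the numbers of genes that rose and fell are given under both scalings where they differ. The 20th percentile of an array averaged log2 2.25 in the LR12 arm at 0 h and 1.64 at 8 h, and changes that reach under it have no defined size. Of the largest changes from 0 h picked for naming, 25 of 54 falls ended and 10 of 50 rises began under the 20th percentile of their group. These include the falls of EPDR1 in each arm, of ZNF660 and CCIN, of CPA3 in the peptide control arm and of NEURL1B in the LR12 arm, and the rises of DLGAP1-AS2 and MARCO. The rise of CCL20 in the LR12 arm began there too.

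**Figure D1:**
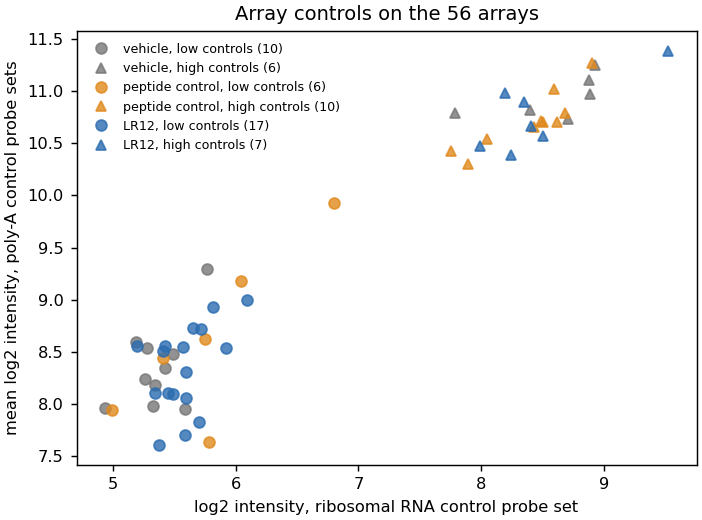
Mean log2 intensity of the poly-A control probe sets against the log2 intensity of the ribosomal RNA control probe set, 1 point per array (56 arrays, coloured by arm). The 33 low-control arrays and the 23 high-control arrays do not overlap on either axis, and both sets hold arrays of each arm.

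In the vehicle arm, the question was how blood changed over the 8 h without LR12. EPDR1, a gene of an ependymin-related lysosomal protein, fell by 8 h (log2 change -3.85 ± 0.73, SE, adjusted p = 0.0149, in 4 of 4 animals). RGS16, a regulator of G protein signalling, fell as well (-2.69 ± 0.50, adjusted p = 0.0126), and the scavenger receptor gene SCARF1 rose by 1.18 ± 0.24 (adjusted p = 0.024). The other genes called at 8 h were DLGAP1-AS2, which rose by 3.64, and SPPL2C and CCIN, which fell by 3.02 and 3.24. At 4 h, the 2 genes called were SPPL2C (-3.05 ± 0.56, adjusted p = 0.0211) and ZNF660 (-3.92 ± 0.77, adjusted p = 0.0471). IL1B, the gene of the cytokine interleukin 1 beta, was 9.62 ± 1.72 (SD, n = 4) at 2 h and 8.51 ± 0.81 at 0 h, and its change of 1.10 ± 0.58 was not called (adjusted p = 0.822, up in 3 of 4 animals).

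At 2 h in the vehicle arm, limma called 0 genes, with 1008 genes at an unadjusted p under 0.05. The smallest p values belonged to DLGAP1-AS2 (3.34), DLX6 (2.92), LCN8 (2.32), IL18RAP (2.14) and TRIM65 (-2.17). With the animal as a block, 12 genes were called at 2 h, 77 at 4 h and 23 at 8 h in the vehicle arm. The array batch as a covariate gave 1, 8 and 7 genes. Leaving out 1 vehicle animal changed these small counts: 3 genes were called at 2 h without Y31301, 1, 1, 0 and 6 at 4 h without Y31301, Y31302, Y31303 and Y31304, and 0 and 1 at 8 h without Y31302 and Y31304.

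Gene lists moved in the vehicle arm although few of their members did. Mature neutrophil markers rose relative to all genes by a median of 0.58 at 2 h (camera adjusted p = 1.59e-06), 0.72 at 4 h (1.66e-07) and 0.50 at 8 h (8.26e-05). None of their 16 measured members was called, and 3 were called at 2 h when adjusted over the list alone. T cell markers fell at 8 h (median relative change -0.61, camera adjusted p = 6.82e-06), with 0 of 21 members called. Eosinophil and basophil markers fell at 8 h (-0.64, adjusted p = 0.0155, 0 of 15 members called), and this was the only comparison in which camera called that list. Camera called 9, 9 and 14 lists at the preset correlation at 2, 4 and 8 h in the vehicle arm, and 0 at each hour with an estimated correlation, as did fry. T cell markers read lower on high-control arrays, but the same 2 of 4 vehicle animals had such arrays at 0 and 8 h.

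**Figure D2:**
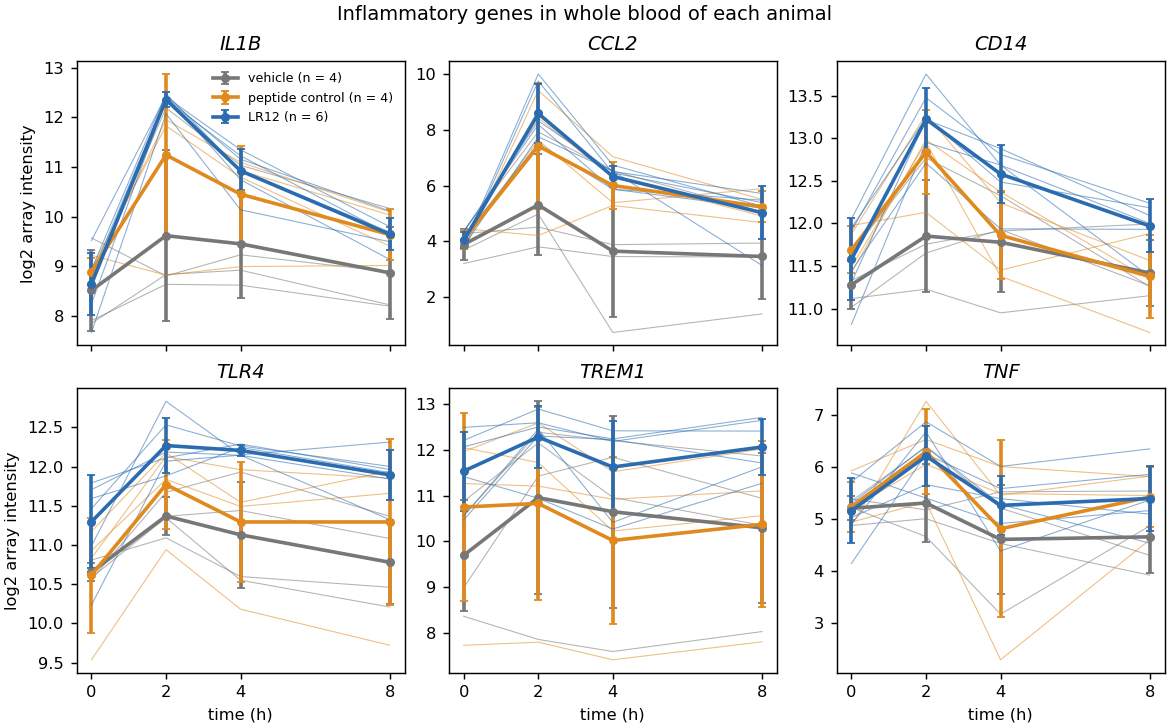
Log2 array intensity of IL1B, CCL2, CD14, TLR4, TREM1 and TNF against time in hours. Thin lines are animals and thick lines are arm means with SD (vehicle n = 4, peptide control n = 4, LR12 n = 6). IL1B peaked at 2 h at 12.36 in the LR12 arm, 11.24 in the peptide control arm and 9.62 in the vehicle arm.

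In the peptide control arm, inflammatory genes rose at 2 h. IL1B rose by 2.35 ± 0.58 (SE, adjusted p = 0.0135) to 11.24 ± 1.63 (SD, n = 4) from 8.89 ± 0.27, in 3 of 4 animals. ICAM1, an adhesion molecule induced by NF-kB, rose by 3.97 ± 0.70 (adjusted p = 0.000714, 3 of 4 animals), and the chemokine gene CCL2 by 3.36 ± 0.82 (adjusted p = 0.0116, 3 of 4). The gene of the protease inhibitor elafin, PI3, rose by 6.26 ± 1.60 (adjusted p = 0.0175, 4 of 4), and NR4A3, a nuclear receptor induced early after stimulation, by 3.89 ± 0.66 (adjusted p = 0.000467, 4 of 4). CD14, the endotoxin co-receptor, rose by 1.15 (adjusted p = 0.0176). IL6 (2.37, adjusted p = 0.121), TLR4 (1.16, adjusted p = 0.0681) and TNF (1.06, adjusted p = 0.342) were not called. CSF1R, the receptor of the monocyte growth factor, fell (-2.77, adjusted p = 0.0131), as did NEURL1B (-3.22) and SASH1 (-3.29). Counted over all genes, 352 rose and 176 fell at 2 h, and 372 and 97 with arrays centred on their median.

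At 4 h, 304 genes rose and 472 fell in the peptide control arm, and 690 rose and 139 fell after centring. PI3 stayed up (6.25 ± 1.60, adjusted p = 0.022), and THBS1 (2.62), a matrix protein released by platelets and monocytes, and IL1RN (2.19), the interleukin 1 receptor antagonist, were up. EPDR1 fell (-4.71 ± 0.73, adjusted p = 0.00064, 4 of 4 animals), as did VMO1 (-4.51), the granzyme genes GZMH (-2.14) and GZMB (-1.83), and CD86 (-2.34), a costimulatory molecule of antigen-presenting cells. By 8 h, 78 genes rose and 39 fell (125 and 21 after centring). MARCO, a scavenger receptor of phagocytes, rose (6.69 ± 1.61, adjusted p = 0.0334) to 8.33 ± 4.06 from 1.64 ± 0.33, a level under the 20th percentile of the arrays, RETN (resistin) by 3.84 (adjusted p = 0.032), and the carbonic anhydrase gene CA4 by 5.11 (adjusted p = 0.0237). CPA3, a mast cell and basophil protease, fell (-5.00 ± 0.88, adjusted p = 0.00394).

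These peptide control counts depended on single animals. Without Y31305 they were 880, 1946 and 558 at 2, 4 and 8 h. Without Y31306 they were 18, 1 and 0, without Y31307 116, 5 and 6, and without Y31308 64, 53 and 22. With the animal as a block the peptide control counts were 1223, 2449 and 688, and with the array batch as a covariate 792, 809 and 366. No peptide control array was a high-control array at 2 h and all 4 were at 4 h, so the 2 h comparison cannot be made within 1 set of arrays. Among high-control arrays alone, 39 genes were called at 4 h and 199 at 8 h.

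Of the lists in the peptide control arm, NF-kB feedback and early response moved most at 2 h, with 10 of 18 members up, 1 down and 7 not called (14 up and 1 down adjusted over the list alone; camera adjusted p = 2.71e-14, and adjusted p = 0.00481 with an estimated correlation). IER3 (4.15), an early response gene, and RELB (3.12), an NF-kB subunit, were among the rises. Inflammatory cytokines (3 of 16 up), chemokines (2 of 17 up) and anti-inflammatory mediators (6 of 17 up, 1 down) also rose, each with an adjusted p of 0.0279 with an estimated correlation. TREM-1 and its adaptor pathway rose (5 of 19 up, adjusted p = 0.00278), which was lost with an estimated correlation (adjusted p = 0.128). TREM2 (2.79), a relative of TREM1, was among its rises. At 4 h, T cell markers fell by a median of 0.92 relative to all genes (2 of 21 members down, 18 adjusted over the list alone, camera adjusted p = 9.59e-07). NK and cytotoxic cell markers fell too (4 of 22 down, adjusted p = 0.00456), and neither held with an estimated correlation (adjusted p = 0.283). T cell markers are lower on high-control arrays, which made up 3 of 4 arrays at 0 h and all 4 at 4 h, and the T cell call was kept with the array batch as a covariate (T cell markers, peptide control 4 h versus 0 h, adjusted p = 9.04e-07). MHC class II presentation fell at 4 h (adjusted p = 0.0355), but not with the array batch as a covariate (adjusted p = 0.052) or with an estimated correlation (adjusted p = 0.431). At 8 h, 13 lists were called, among them ribosomal proteins (down, 3 of 38 called, adjusted p = 1.00e-09) and inflammasome genes (up, 0 of 18 called, adjusted p = 0.0175), and none held with an estimated correlation.

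In the LR12 arm, which had 6 animals against 4 and so more power, inflammatory genes rose at 2 h. IL1B rose by 3.72 ± 0.47 (SE, adjusted p = 4.61e-08) to 12.36 ± 0.14 (SD, n = 6) from 8.64 ± 0.63. ICAM1 rose by 5.49 ± 0.57 (adjusted p = 7.53e-10) to 11.98 ± 0.52 from 6.49 ± 0.36, and CCL2 by 4.56 ± 0.67 (adjusted p = 6.57e-07) to 8.59 ± 1.04 from 4.03 ± 0.28. The elafin gene PI3 rose most, by 7.70 ± 1.30 (adjusted p = 1.02e-05), and genes stored in neutrophil granules rose with it, such as CRISP3 (6.50 ± 1.32, adjusted p = 0.000146), OLFM4 (6.49 ± 1.46, adjusted p = 0.000475) and lactotransferrin, LTF (5.55 ± 1.02, adjusted p = 3.8e-05). The inflammasome cytokine gene IL18 rose by 4.64 ± 0.57 (adjusted p = 1.89e-08), TNFAIP3, a brake on NF-kB, by 3.60 ± 0.43 (adjusted p = 9.55e-09), and CD14 by 1.65 ± 0.24 (adjusted p = 6.42e-07). Each of these rose in 6 of 6 animals. TNF (1.05 ± 0.43, adjusted p = 0.057, up in 5 of 6), IL6 (1.09 ± 0.69, adjusted p = 0.25, 5 of 6) and TREM1 (0.74 ± 0.84, adjusted p = 0.561, 5 of 6) were not called.

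Single genes expressed in monocytes, dendritic cells and lymphocytes fell at 2 h in the LR12 arm, while the list of monocyte markers was not called (4 of 16 up, 7 down, camera adjusted p = 0.571). CSF1R fell by 4.16 ± 0.56 (adjusted p = 1.27e-07), the adenosine receptor gene ADORA2B by 4.52 ± 0.51 (adjusted p = 3.23e-09), and the fractalkine receptor gene CX3CR1 by 3.05. NEURL1B, an E3 ubiquitin ligase gene, fell under the 20th percentile of the arrays, to 0.63 ± 1.58 from 8.15 ± 0.83 (adjusted p = 7.26e-10). The size of its fall is therefore not defined, at -7.52 ± 0.77 as deposited and -5.59 with an offset added before the log (NEURL1B, LR12 2 h versus 0 h). LILRA4 (-3.25) of plasmacytoid dendritic cells, GZMH (-2.62) of cytotoxic cells, LCK (-2.39) and CD27 (-2.17) of T cells, CD79A (-2.13) of B cells and CD74 (-2.44), the MHC class II chaperone, fell in every animal. The glucocorticoid-induced gene TSC22D3 also fell (-2.15), as did FOS (-4.16).

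At 4 h in the LR12 arm, OLFM4 (7.80 ± 1.46, adjusted p = 3.56e-05) and MARCO (7.76 ± 1.32, adjusted p = 8.56e-06) were among the largest rises, as was the Fc receptor gene FCGR1A (5.69 ± 0.98, adjusted p = 1.16e-05). The interferon-induced chemokine gene CXCL10 rose by 4.10 and the regulator IRF7 by 1.55. IL1B was still up (2.28 ± 0.47, adjusted p = 0.000139), as were CCL2 (2.29, adjusted p = 0.005) and TLR4, the endotoxin receptor (0.91, adjusted p = 0.0131). LCK fell by 3.48 ± 0.48 (adjusted p = 2.52e-07), and FASLG (-3.31), CD247 (-3.19) and the T cell chemokine gene CCL5 (-3.06) fell with it. EPDR1 fell by 5.05 ± 0.60 (adjusted p = 1.19e-08). At 8 h, MARCO rose to 10.70 ± 0.80 from 1.41 ± 0.37 (adjusted p = 1.48e-06), a starting level under the 20th percentile of the arrays. Its rise was 9.29 ± 1.32 as deposited and 8.0 with an offset added before the log (MARCO, LR12 8 h versus 0 h). CA4 rose by 6.71 ± 0.92 (adjusted p = 8.98e-07) and RETN by 4.75 ± 0.75 (adjusted p = 7.04e-06), and all 3 rose in 6 of 6 animals. The mast cell chymase gene CMA1 fell by 4.50 ± 0.50 (adjusted p = 2.01e-08), and CPA3 by 3.86. IL1B (1.0 ± 0.47, adjusted p = 0.108, up in 5 of 6), CCL2 (1.0, adjusted p = 0.276), CD14 (0.39, adjusted p = 0.232) and TLR4 (0.60, adjusted p = 0.13) were not called at 8 h.

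Over all genes, 1613 rose and 3512 fell at 2 h, 1731 and 4168 at 4 h, and 1386 and 3272 at 8 h in the LR12 arm. The excess of falls depended on the scaling. With centred arrays 2094 rose and 2687 fell at 2 h, 2713 and 2685 at 4 h, and 2212 and 1797 at 8 h, and with quantile normalization 1881 and 3011, 2179 and 3260, and 1705 and 2395. The array batch as a covariate gave LR12 totals of 5620, 6069 and 4424, and on low-control arrays alone 5307, 5212 and 3702.

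NF-kB feedback and early response led the lists of the LR12 arm at 2 h, with 16 of 18 members up, 1 down and 1 not called (camera adjusted p = 2.89e-14, and adjusted p = 0.00487 with an estimated correlation). Chemokines (8 of 17 up, 1 down), among them CCL20 (4.50) and CCL4 (3.68), and anti-inflammatory mediators (10 of 17 up, 3 down), among them IL1RN (3.61) and IL4R (3.02), held with an estimated correlation (adjusted p = 0.0434). Endotoxin recognition rose at 4 h (9 of 17 up, 1 down, adjusted p = 3.43e-05), with LY96 (2.64), the TLR4 partner, among the rises, but not with an estimated correlation (adjusted p = 0.0937). Mature neutrophil markers had 12 of 16 members up at each hour and 1 down at 4 and 8 h, with S100A12 (3.37 at 2 h) and PROK2 (3.59 at 4 h). This list held with an estimated correlation at 8 h alone (adjusted p = 0.0255), as did monocyte markers (9 of 16 up, 1 down, adjusted p = 0.0255), with CD36 (3.13) and CD163 (1.65), and leukocyte adhesion and migration (6 of 22 up, 1 down, adjusted p = 0.0111), with ITGAM (1.60) and CCR1 (2.60). The neutrophil granule genes rose at 2 h (12 of 18 up, 13 adjusted over the list alone, adjusted p = 4.53e-08), and coagulation and fibrinolysis at 8 h (4 of 15 up, adjusted p = 0.0136). Glucocorticoid-responsive genes rose at 8 h (7 of 20 up, 3 down, adjusted p = 0.00425), as did glycolysis and hypoxia genes (10 of 28 up, 5 down, adjusted p = 0.00017), led by LDHA (2.32). None of these 4 lists passed with an estimated correlation (adjusted p = 0.0551 to 0.0679).

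T cell markers fell in full at 4 h, with 21 of 21 members down and a median of -2.01 relative to all genes (camera adjusted p = 5.7e-12, adjusted p = 0.126 with an estimated correlation). At 2 h 15 of the 21 were down (19 adjusted over the list alone), and at 8 h 19. B cell markers fell at 2 h (14 of 19 down, adjusted p = 9.09e-05), with EBF1 (-2.46), and NK and cytotoxic cell markers at each hour (11, 13 and 12 of 22 down). MHC class II presentation fell at 2 h (11 of 14 down, adjusted p = 7.53e-05), with HLA-DPA1 (-2.31), and so did dendritic cell markers (10 of 16 down, 1 up, adjusted p = 0.011). Cell cycle genes fell (15, 18 and 21 of 25 down, 1 up at 2 h), among them TOP2A (-2.62 at 8 h), and heat shock genes fell at 2 h (10 of 22 down, 2 up, adjusted p = 0.0407). None of these falls held with an estimated correlation, and fry called each of them. T cell, B cell, NK and cell cycle medians are lower by 0.44 to 0.48 on high-control arrays. Each, with the array batch as a covariate, kept its call except MHC class II presentation at 8 h (adjusted p from 0.046 to 0.0746).

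Some lists moved little or both ways in the LR12 arm. Ribosomal proteins had 23 of 38 members down and 1 up at 4 h, such as RPL36 (-1.15), yet their median was only 0.07 below that of all genes (adjusted p = 0.000202, lost with an estimated correlation at 0.35). Proteasome genes rose at 4 h (9 of 31 up, 4 down, adjusted p = 0.00877), with PSMC6 (2.46), and apoptosis genes at 4 h (8 of 20 up, 2 down, adjusted p = 0.00858). The interferon response rose at 4 h (7 of 28 up, adjusted p = 0.000721), and it reads 0.30 higher on high-control arrays. With an estimated correlation these calls at 4 h were lost (adjusted p = 0.287, 0.126 and 0.438 in turn). Inflammatory cytokines rose at 2 h (4 of 16 up, 2 down, adjusted p = 0.0163), which was lost as well (adjusted p = 0.0816).

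**Figure D3:**
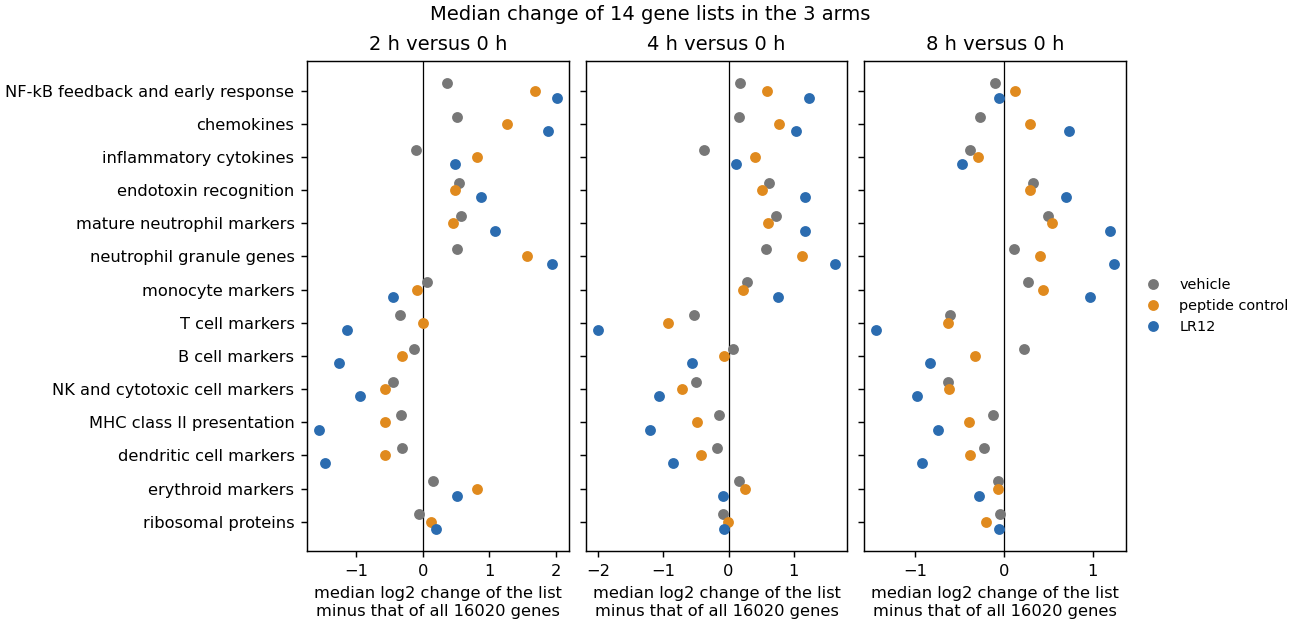
Median log2 change from 0 h of 14 gene lists, minus the median of all 16020 genes, at 2, 4 and 8 h (1 point per arm). At 4 h T cell markers lay at -2.01 in the LR12 arm, -0.92 in the peptide control arm and -0.53 in the vehicle arm, and the lymphocyte lists read lower on high-control arrays.

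The arms were compared at 0 h to see whether they started alike. Against both control arms, limma called 0 genes at 0 h for LR12, with 899 at an unadjusted p under 0.05. Against the peptide control it also called 0 genes (762), and against vehicle 2 were higher and 1 lower. The peptide control against vehicle gave 0 genes (433). Erythroid markers were lower in LR12 animals than in both control arms already at 0 h, by a median of 0.72 relative to all genes (camera adjusted p = 2.79e-09, 0 of 18 members called, 4 adjusted over the list alone), which was lost with an estimated correlation (adjusted p = 0.228). The carbonic anhydrase gene CA1, abundant in red cells, was 10.68 ± 0.79 (SD, n = 6) in LR12 animals, 12.27 ± 0.36 (n = 4) in vehicle animals and 11.76 ± 0.53 (n = 4) in peptide control animals. The alpha-globin chaperone gene AHSP was 6.70 ± 0.57, 7.69 ± 0.42 and 7.54 ± 0.57. Monocyte markers were lower (adjusted p = 0.0176) and NK markers (adjusted p = 0.000926) and heat shock genes (adjusted p = 0.0024) higher in LR12 animals. None of these 3 held with an estimated correlation (adjusted p = 0.449) or with fry, and the call of the monocyte list was lost with the array batch as a covariate (adjusted p = 0.0619). Leaving out Y31307, Y31311 or Y31312 gave 1 gene at 0 h for LR12 against both control arms, and leaving out Y31309 gave 1 gene against the peptide control. Against vehicle the 3 genes became 5 without Y31303, 0 without Y31304, Y31310 or Y31314 and 1 without Y31309, and the peptide control against vehicle gave 2 genes without Y31303.

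LR12 was compared with both control arms at each hour to see how the treated animals differed. Since the labels leave open whether vehicle animals received endotoxin, differences from vehicle, or from both control arms together, cannot be separated from an effect of the challenge itself. IL1B, CCL2, ICAM1 and CD14 are no exception. At 2 h ICAM1 was higher by 3.18 ± 0.53 (SE, adjusted p = 9.26e-05), at 11.98 ± 0.52 (SD, n = 6) against 8.79 ± 2.69 (n = 8). IL1B was higher by 1.93 ± 0.44 (adjusted p = 0.00222), at 12.36 ± 0.14 against 10.43 ± 1.78. IL18 (2.37, adjusted p = 0.00182), CCL2 (2.23, adjusted p = 0.0105), SLAMF1 (2.45 ± 0.44, adjusted p = 0.000187), a receptor on activated lymphocytes and phagocytes, and CD14 (0.88, adjusted p = 0.00538) were higher too. ABHD10, a mitochondrial thioesterase gene, was lower by 2.35 ± 0.27 (adjusted p = 1.72e-07), at 6.14 ± 0.74 in LR12 animals, 8.79 ± 0.52 in vehicle and 8.18 ± 0.36 in peptide control animals, although it was 9.17 ± 0.28, 8.99 ± 0.73 and 8.87 ± 0.31 at 0 h. CD36 (-2.87), HLA-DPB1 (-1.99) and AHSP (-1.72, adjusted p = 0.000473) were lower. TREM1 (1.39 ± 0.79, adjusted p = 0.247), TLR4 (0.70, adjusted p = 0.0786) and TNF (0.41, adjusted p = 0.554) were not called.

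At 4 h ICAM1 was higher by 3.0 ± 0.53 (adjusted p = 0.000469), CXCL10 by 2.75 (adjusted p = 0.00156), SOCS1, a feedback inhibitor of cytokine signalling, by 1.74, IRF7 by 1.39, TLR4 by 0.99 ± 0.28 (adjusted p = 0.0166) and CD14 by 0.76 (adjusted p = 0.0227). The T cell transcription factor genes BCL11B (-1.91, adjusted p = 0.000469) and LEF1 (-1.78) and the integrin gene ITGA4 (-2.45) were lower. At 8 h the glycolytic gene PGAM1 was higher by 0.95 ± 0.15 (adjusted p = 0.000343). The mitochondrial carrier gene SLC25A39 (-2.18, adjusted p = 0.000343), CA1 (-1.93, adjusted p = 0.000441), ALAS2 (-1.52, adjusted p = 0.00148), which starts heme synthesis in red cell precursors, and the cell cycle gene CDCA3 (-2.50 ± 0.48, adjusted p = 0.00321) were lower. CA1, AHSP and SLC25A39 had lower means in LR12 animals at 0 h as well, uncalled, and TLR4 a mean higher by 0.66 at 0 h, uncalled, so much of its difference was there at the start. On each animal's mean over 2, 4 and 8 h, ICAM1 was higher by 2.29 ± 0.40 (adjusted p = 0.0113), CD14 by 0.74 ± 0.16 (adjusted p = 0.0199), the receptor gene GPR84 by 1.51 ± 0.37 (adjusted p = 0.0269) and TLR4 by 0.85 (adjusted p = 0.0349). TREM1 was not called (1.47 ± 0.70, adjusted p = 0.187).

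For LR12 against both control arms, 587 genes were higher and 2030 lower at 2 h, 556 and 1062 at 4 h, 55 and 218 at 8 h, and 380 and 1297 on the mean of the hours. After centring these were 813 and 1351, 671 and 713, 118 and 96, and 563 and 779. The array batch as a covariate gave 2867, 2912 and 1163 genes at 2, 4 and 8 h, and 2938 on the mean. Among high-control arrays alone, 63 genes were called at 4 h and 34 at 8 h. With the animal as a block 483 genes were called at 8 h. Quantile normalization gave 89 genes at 8 h, and 767 lower and 360 higher genes on the mean.

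Animals of every arm moved the numbers for LR12 against both control arms. At 4 h the 1618 genes became 1027 without Y31301, 943 without Y31304, 979 without Y31305, 841 without Y31312, 893 without Y31313 and 2904 without Y31303. At 8 h the 273 genes became 71, 86, 1887, 81, 96, 175 and 163 without Y31301, Y31302, Y31303, Y31304, Y31305, Y31306 and Y31308. Among LR12 animals, they became 1090, 89, 142, 65, 101 and 134 without Y31309, Y31310, Y31311, Y31312, Y31313 and Y31314. At 2 h 1679 genes were called without Y31312. On the mean over the hours, the 1677 genes became 483, 686, 3669, 455 and 713 without Y31301 to Y31305 in turn, and 2645, 267, 226, 251 and 398 without Y31309, Y31310, Y31312, Y31313 and Y31314.

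NF-kB feedback and early response was higher in LR12 animals than in both control arms at 2 h, with 14 of 18 members higher, 1 lower and 3 not called (15 and 1 adjusted over the list alone; camera adjusted p = 3.95e-13, and adjusted p = 0.00822 with an estimated correlation). Leukocyte adhesion and migration was higher at 8 h (1 of 22 called, adjusted p = 0.00211, and adjusted p = 0.0209 with an estimated correlation). TREM-1 and its adaptor pathway was higher at 2 h (6 of 19 higher, 1 lower, adjusted p = 5.56e-05), with TREM2 (2.15), but not with an estimated correlation (adjusted p = 0.0701). Proteasome genes were higher at 4 h (6 of 31, adjusted p = 1.02e-05, adjusted p = 0.135 with an estimated correlation). T cell markers were lower at 4 h (11 of 21 members, 16 adjusted over the list alone, adjusted p = 1.23e-09), with LEF1 and CD3G (-1.46), B cell markers at 2 h (10 of 19, adjusted p = 2.16e-05), MHC class II presentation at 2 h (9 of 14, adjusted p = 5.56e-05) and cell cycle genes at 8 h (7 of 25, adjusted p = 1.3e-09), with TOP2A (-1.64). Erythroid markers were lower at each hour (6, 8 and 6 of 18 members, 1 higher at 2 h) and on the mean (10 of 18, 1 higher, adjusted p = 1.47e-05), with AHSP, CA1 and BPGM (-1.42). None of these last 5 lists held with an estimated correlation. Array control genes were higher at 8 h (1 of 14, adjusted p = 0.0496), which was lost with the array batch as a covariate (adjusted p = 0.0563) and with an estimated correlation (adjusted p = 0.172).

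The scrambled peptide was the sequence control for LR12. At 2 h HAMP, the gene of the iron-regulating hormone hepcidin, was higher in LR12 animals by 2.27 ± 0.40 (SE, adjusted p = 0.00138, n = 6 against 4), PLEK (pleckstrin) by 1.93 ± 0.42 (adjusted p = 0.00967), SLAMF1 by 1.82 and THBD (thrombomodulin), an anticoagulant receptor, by 0.96 (adjusted p = 0.00862). BOLA3 was lower by 2.58 ± 0.37 (adjusted p = 0.000123), NEURL1B by 4.08 ± 0.86 (adjusted p = 0.00706, and 0.0555 with an offset added before the log), CD99 by 1.28 (adjusted p = 0.00018), AHSP by 2.16 (adjusted p = 0.00223), CD163 by 1.54 and HLA-DRA by 0.83. Almost no gene was called at 2 h with only the arrays compared. IL1B (1.12 ± 0.53, adjusted p = 0.254), TNF (-0.08 ± 0.48, adjusted p = 0.956), IL6 (-0.66, adjusted p = 0.72), CCL2 (1.17, adjusted p = 0.431) and TREM1 (1.45 ± 0.94, adjusted p = 0.444) were not called at 2 h in the main fit. The 95% interval ran from 0.05 to 2.19 for IL1B and from -1.06 to 0.89 for TNF.

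GJB2, a connexin gene, was higher in LR12 than in peptide control animals at 2 h (3.14 ± 0.70, adjusted p = 0.00967), 4 h (3.57 ± 0.70, adjusted p = 0.00878) and 8 h (3.68 ± 0.70, adjusted p = 0.0416), but at 0 h it already stood at 5.47 ± 1.59 (SD, n = 6) in LR12, 2.31 ± 0.74 (n = 4) in peptide control and 5.54 ± 0.12 (n = 4) in vehicle animals. At 4 h PDE7A, a phosphodiesterase of T cells (-2.28, adjusted p = 0.00395), ITGA4 (-2.11), LEF1 (-1.73) and CD3G (-1.36) were lower. The other genes called at 8 h were RFESD (-1.42 ± 0.29) and the kinetochore gene SPC25 (-2.51 ± 0.49), both at an adjusted p of 0.0416. TREM1 was not called at 4 h (1.60, adjusted p = 0.421) or 8 h (1.69 ± 0.94, adjusted p = 0.534).

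Against the peptide control, 38 genes were higher and 434 lower in LR12 animals at 2 h, 60 and 157 at 4 h, and 1 and 2 at 8 h. Centred arrays gave 26 and 122, 61 and 95, and 1 and 0, and quantile normalization 30 and 229, 55 and 87, and 0. Counts were 658, 318 and 14 with the array batch as a covariate, and 726, 297 and 10 with the animal as a block. With only the arrays compared, 1 gene was called at 2 h, 0 at 8 h and fewer at 4 h. Low-control arrays alone gave 693 genes at 2 h, and high-control arrays 15 at 4 h and 1 at 8 h. The 472 genes at 2 h became 113, 153, 139 and 218 without peptide control animals Y31305 to Y31308, and 1390, 151, 299, 133, 140 and 180 without LR12 animals Y31309 to Y31314 in turn. At 4 h the 217 genes became 22, 102, 27 and 72 without Y31305 to Y31308 in turn, and 426, 14, 24 and 95 without Y31309, Y31312, Y31313 and Y31314. At 8 h the 3 genes became 63 without Y31309, 5 without Y31313, 1 without Y31306 or Y31308, and 0 without Y31307, Y31310 or Y31314.

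Of the 14 lists called between LR12 and the peptide control at 2 h, 7 were lower and 7 higher in LR12 animals. T cell markers (0 of 21 called, 9 lower adjusted over the list alone, median -0.72 relative to all genes, camera adjusted p = 5.08e-06), B cell markers (1 of 19 lower, adjusted p = 2.94e-05), erythroid markers (3 of 18 lower, adjusted p = 0.000351), MHC class II presentation (3 of 14 lower, adjusted p = 0.000214) and cell cycle genes (3 of 25 lower, adjusted p = 3.83e-05) were lower. Oxidative phosphorylation was lower (1 of 35, adjusted p = 0.0423), which was lost with the array batch as a covariate (adjusted p = 0.0701). Ribosomal proteins were lower too (adjusted p = 0.029). NF-kB feedback and early response was higher (0 of 18 called, 1 adjusted over the list alone, adjusted p = 1.4e-05). The TREM-1 pathway (adjusted p = 0.00172), endotoxin recognition (0.00947), inflammasome genes, glycolysis and hypoxia genes, mature neutrophil markers and the interferon response (adjusted p of 0.011 to 0.0197) were higher as well, with 0 members called in each. Platelet markers were lower at 8 h (0 of 17 called, 1 adjusted over the list alone, adjusted p = 0.00174). No list held with an estimated correlation at 0, 2, 4 or 8 h, where the smallest adjusted p was 0.159 at 8 h. At 0 h LR12 and peptide control animals also differed in 8 lists at the preset correlation, among them T cell markers (higher in LR12 animals, adjusted p = 0.00376, and 0.169 with the array batch as a covariate).

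Against vehicle, LR12 animals had 738 genes higher and 1806 lower at 2 h, 699 and 1211 at 4 h, and 149 and 286 at 8 h. After centring the numbers were 944 and 1224, 853 and 854, and 171 and 142. IL1B was higher at 2 h by 2.74 ± 0.53 (SE, adjusted p = 0.000357), CCL2 by 3.28 ± 0.74 (adjusted p = 0.00175) and CD14 by 1.37 ± 0.27 (adjusted p = 0.000395), and at 4 h TLR4 by 1.08 ± 0.33 (adjusted p = 0.0267, with an uncalled 0.64 at 0 h). NF-kB feedback and early response (15 of 18 higher, 1 lower, adjusted p = 0.00133 with an estimated correlation), inflammatory cytokines (4 of 16 higher, 2 lower) and the TREM-1 pathway (5 of 19 higher, 1 lower) were higher at 2 h, the last pair at an adjusted p of 0.0424 with an estimated correlation. LR12 against vehicle gave 2871, 2978 and 1174 genes with the array batch as a covariate, and on low-control arrays alone 3087, 2393 and 1895. With the animal as a block 744 genes were called at 8 h. Leaving out vehicle animals moved LR12 against vehicle to 1392, 709 and 53 genes without Y31301 at the 3 hours, 1511, 897 and 63 without Y31302, 1476, 709 and 107 without Y31304, and 3718 at 4 h and 2668 at 8 h without Y31303. At 8 h it gave 1080, 208, 213, 143 and 224 genes without LR12 animals Y31309 to Y31313 in turn.

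The peptide control arm was compared with vehicle to see what the scrambled peptide arm had without LR12. At 4 h, 1 gene was called, KYNU, the gene of an enzyme of tryptophan breakdown, higher by 1.38 ± 0.25 (SE, adjusted p = 0.0145), at 11.09 ± 0.06 (SD, n = 4) against 9.71 ± 0.46 (n = 4). Limma called 0 genes at 2 h (1339 at an unadjusted p under 0.05) and 0 at 8 h (1153). The smallest p values at 2 h included IL18 (3.28), ICAM1 (3.27) and NFKBIA (1.40), the NF-kB inhibitor, each at an adjusted p of 0.0706. NF-kB feedback and early response was higher in the peptide control arm at 2 h (0 of 18 called, 10 adjusted over the list alone, camera adjusted p = 4.29e-15, and adjusted p = 0.00336 with an estimated correlation), as were inflammatory cytokines (3 adjusted over the list alone, adjusted p = 0.0236 with an estimated correlation). These counts rested on single animals. Without Y31303 638 genes were called at 2 h, 1029 at 4 h and 221 at 8 h, and without Y31305 383, 257 and 53. The 1 gene at 4 h became 0 without Y31302, Y31306 or Y31307 and 5 without Y31308, and at 8 h 3 genes were called without Y31304 and 1 without Y31307. Counts were 16, 3 and 4 with the array batch as a covariate, and 0, 4 and 4 with the animal as a block.

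Whether the response itself differed was tested as the difference between LR12 and both control arms in the change from 0 h. The difference was positive in 69 called genes and negative in 397 at 2 h, in 8 and 16 at 4 h, and in 2 and 3 at 8 h. A negative difference is a smaller rise or a larger fall in the LR12 arm, so these numbers do not count weaker responses. After centring the numbers were 29 and 77, 4 and 14, and 0, and after quantile normalization 56 and 264, 12 and 18, and 0. IL1B rose by 1.99 ± 0.63 more in the LR12 arm at 2 h but was not called (adjusted p = 0.0642), and CCL2 by 2.17 ± 0.88 (adjusted p = 0.142). With the animal as a random block both were called (adjusted p = 0.00875 and 0.0452). The TREM1 difference in change was 0.08 ± 1.11 (adjusted p = 0.982), and its 95% interval ran from -2.17 to 2.32 without a block and from -0.73 to 0.89 with the animal as a fixed block (SE 0.40). NF-kB feedback and early response rose more in the LR12 arm at 2 h (3 of 18 called with a positive and 1 with a negative difference, 10 and 1 adjusted over the list alone, adjusted p = 0.0429 with an estimated correlation). Leukocyte adhesion and migration rose more at 8 h (0 of 22 called, adjusted p = 0.0136 with an estimated correlation). T cell markers fell more at 4 h (0 of 21 called, 18 adjusted over the list alone, camera adjusted p = 1.51e-11, lost with an estimated correlation at 0.224).

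The count of genes whose change differed moved with the fit. With the animal as a block it was 2020, 897 and 242 at 2, 4 and 8 h, with the array batch as a covariate 117, 74 and 5, and with both 1019, 1313 and 74. For the change from 0 h to 2 h, the 466 genes became 303, 1171, 43, 73, 300 and 132 without control animals Y31301, Y31303, Y31304, Y31305, Y31306 and Y31308, and 835, 123, 74, 41, 80 and 151 without LR12 animals Y31309 to Y31314 in turn. At 4 h the 24 genes became 9, 15, 649, 3, 6, 39 and 1 without Y31301 to Y31306 in turn and Y31308, and 44, 2, 3, 1, 2 and 13 without Y31309 to Y31314 in turn. At 8 h the 5 genes became 125 without Y31303, 1 without Y31308, Y31310 or Y31312, and 0 without Y31301, Y31302, Y31304, Y31305, Y31306, Y31311, Y31313 or Y31314.

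TREM1 was not called in any comparison. It was lowest at every hour in control animals Y31303 (7.60 to 8.37) and Y31306 (7.42 to 7.81). Its difference between LR12 and both control arms at 2 h had a 95% interval from -0.20 to 2.97. TREML1 fell by 1.08 at 8 h in the LR12 arm, in 6 of 6 animals (by 0.79 to 1.35). The unpaired fit did not call this fall (adjusted p = 0.0618), and the fit with the animal as a block did (TREML1, LR12 8 h versus 0 h, adjusted p = 0.0101). At 8 h TREML1 also fell in 3 of 4 peptide control animals, all but Y31305, and it rose in 4 of 4 vehicle animals, both uncalled. LR12 and the peptide control did not differ in a call at 8 h (-0.66, adjusted p = 0.66). TYROBP, the gene of the TREM-1 adaptor, changed by 0.10 at 2 h (adjusted p = 0.622). CXCL8, the neutrophil chemokine, changed by 0.50 at 2 h in the LR12 arm (adjusted p = 0.336).

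Each animal's change was also set against the mean change of the LR12 animals, as the slope over all genes, with an LR12 animal set against the others of its arm. A slope of 1 means a change as large as that mean. At 2 h the slopes were 0.217 ± 0.189 (SD, n = 4) in the vehicle arm, 0.430 ± 0.294 (n = 4) in the peptide control arm and 0.809 ± 0.118 (n = 6) in the LR12 arm. At 4 h they were 0.274 ± 0.235, 0.532 ± 0.289 and 0.825 ± 0.127, and at 8 h 0.271 ± 0.232, 0.477 ± 0.310 and 0.751 ± 0.123. Vehicle animal Y31303 had 0.447, 0.587 and 0.610, and peptide control animal Y31305 had -0.0014, 0.127 and 0.0776. Genes are not independent replicates, and since the slope is taken along the LR12 change, it does not rank the arms by the size of their own change.

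**Figure D4:**
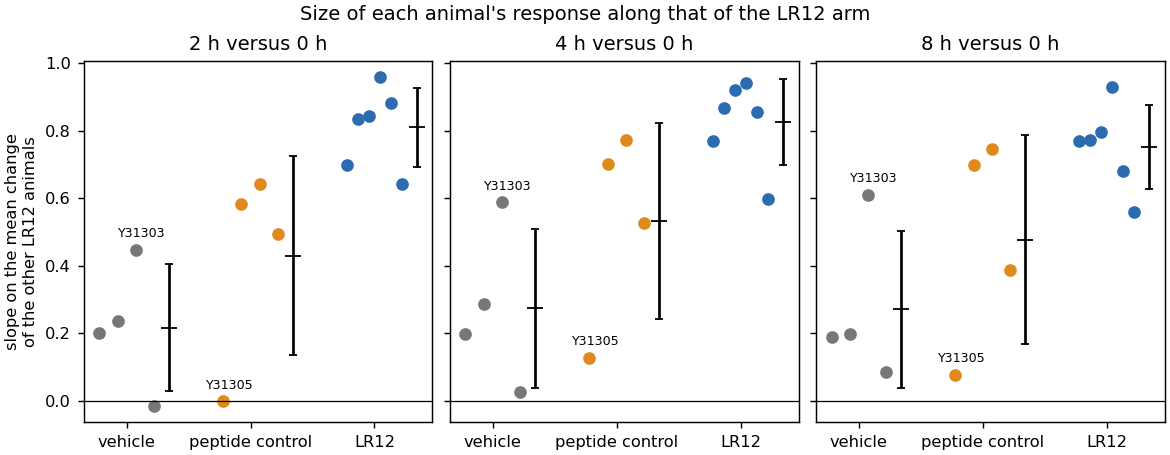
Slope over all genes of each animal's log2 change from 0 h on the mean change of the other LR12 animals, at 2, 4 and 8 h (points are animals, bars mean and SD). LR12 animals lay between 0.641 and 0.957 at 2 h, while Y31305 of the peptide control arm lay at -0.0014 and Y31303 was the highest of the vehicle arm at 0.447.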

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

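The test of RNA quality on the arrays of Y31305 was set before its result was seen. The other tests weighed in this part, and the counts over other splits of the samples, were written after the results were seen.

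Single animals stood far from the rest of their group in 18 of the 177 groups of 4 or 6 values tested (10.2%), where chance alone gives about 1 in 20. Gene levels made up 14 of the 120 tested. In vehicle animals, IL1B at 2 h was 12.19 in Y31303 and 8.63 to 8.83 in the others, and CXCL8 at 4 h was 6.49 in Y31303 and 5.11 to 5.21 in the others. IL6 at 4 h was 4.62 in Y31301 and 1.67 to 1.91 in the others, and CD14 at 8 h was 11.99 in Y31301 and 11.15 to 11.27 in the others. In peptide control animals, IL1B in Y31305 was 8.82 at 2 h and 8.99 at 4 h, where the others had 11.83 to 12.37 and 10.79 to 11.09. TNF at 4 h was 2.28 in Y31305, near the 20th percentile of that array, and 5.46 to 6.01 in the others. CXCL8 at 8 h was 5.20 in Y31305 and 6.34 to 6.47 in the others. TLR4 at 8 h was 9.72 in Y31308 and 11.66 to 11.94 in the others.

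In LR12 animals, Y31311 had TREM1 at 10.94 at 2 h, where the others had 12.30 to 12.89, and TREML1 at 7.99 at 4 h, where the others had 9.41 to 9.91. In Y31309, IL1B at 2 h was 12.08 (12.35 to 12.48 in the others) and CD14 at 8 h was 11.38 (11.93 to 12.24). CCL2 at 8 h was 3.13 in Y31310 and 5.19 to 5.72 in the others. Among array measures, 4 of 48 stood apart. The 20th percentile was 4.19 on the 2 h array of Y31302 (4.55 to 4.58 in the other vehicle animals) and 6.20 on the 4 h array of Y31314 (2.66 to 3.52 in the other LR12 animals). The actin 3' to 5' log2 ratio of Y31305 at 8 h was 2.50 (0.936 to 1.19 in its arm), but this was a low-control array and the others were high-control arrays. It lay within the low-control arrays of other animals (up to 2.77). The GAPDH ratio of Y31311 at 0 h was 0.796 (1.22 to 1.44). Over the 342 named genes, 356 of 4104 groups met the same criterion (8.67%), most often through Y31303 (68) and Y31309 (46).

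The change from 0 h differed between LR12 and both control arms by a test of the difference itself, in 466 genes at 2 h, 24 at 4 h and 5 at 8 h. Of the 8093 kept probe sets without a single gene symbol, which no comparison of genes used, 379 were called between LR12 and both control arms at 2 h, 107 higher and 272 lower.

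The first pattern weighed was that Y31303 and Y31305 stood apart from their arms in inflammatory genes. Of the 9 groups of response slopes, 0 met the criterion. Of the 35 splits of the 8 control animals into 4 and 4, the split that exchanges these animals called the most genes at 3 of 3 hours. These animals were picked for their responses, so that split restates the pattern and supports no explanation. An exchange of the arm labels of Y31303 and Y31305 cannot be told apart from a low response in Y31305 and a high one in Y31303. For Y31303 an array batch is argued against, since Y31303 and Y31304, whose arrays shared a batch at every hour, differed in slope by 0.461 or more, above 0.236 to 0.255 (2 SD of the LR12 arm). At 2 h, where IL1B set both animals apart, all arrays of both arms were low-control arrays. Degraded RNA on the arrays of Y31305 cannot be told apart, since 1 of its 4 arrays, that of 4 h at 1.79, lay outside the actin 3' to 5' ratios of its batch.

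The second pattern was that LR12 animals differed from the peptide control at 2 h. A difference already present at 0 h is argued against, since over the called genes the difference at 0 h was 0.0254 of that at 2 h (from -0.0312 to 0.084 without each animal). Animal Y31305 alone is argued against, since without it the median difference stayed at 0.931 of its size, although the count fell to 113. An array batch is argued against, since low-control arrays alone called 693 genes. With only the arrays compared, almost no gene was called. A difference due to LR12 is open as a hypothesis, as are chance and other differences between the animals of the arms.

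The third pattern was that more genes fell than rose in the LR12 arm at 4 h. With arrays centred on their median, 49.7% of the calls were falls, against 70.7% without. Centring itself sets the median change near 0, so this cannot decide whether the scaling of the arrays made the excess, which stays open. With quantile normalization 2179 rose and 3260 fell. The array batch as a covariate left 69.7%, which argues against the batch.

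Other splits of the same arrays show which counts chance can give. Within the LR12 arm chance can be excluded, as only the real split of 100 called as many genes (1 of 100 at 2, 4 and 8 h). The real counts were 5125, 5899 and 4658, and the highest others 3847, 3392 and 1802. Among the 32 splits drawn that part every animal's arrays, as the real one does, the highest others were 2476, 3392 and 1802. In the peptide control arm the 35 splits mix the arrays of paired animals. Against these splits alone chance can be excluded at 2 h (1 of 35, 528 against 349) and 4 h (1 of 35, 776 against 465) but not at 8 h (2 of 35, 117 against 456). Only 8 splits part every animal's arrays there, too few for a share under 0.05, and their highest others were 232, 63 and 36. With the pairing kept, the splits therefore do not decide. In the vehicle arm the count at 2 h was 0, which 35 of 35 splits reach by construction (highest other 11), so nothing is decided there. At 4 h (3 of 35, 2 against 753) and 8 h (2 of 35, 6 against 1980) chance cannot be excluded against the splits that mix paired arrays. Among the 8 that part every animal's arrays, too few for a share under 0.05, the highest others were 0, 3 and 3. The splits with 753 and 1980 genes set Y31301 and Y31302 against Y31303 and Y31304. At 0, 4 and 8 h the former had low-control and the latter high-control arrays, so these splits follow the array batch exactly, and batch and animals cannot be told apart there. With the batch as a covariate the real vehicle counts were 1, 8 and 7. In the peptide control arm, the split with 456 genes at 8 h sets both low-control arrays on 1 side.

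Between arms, chance can be excluded for LR12 against both control arms at 2 h (1 of 100, 2617 against 1123), 4 h (1 of 100, 1618 against 1539), 8 h (2 of 100, 273 against 1660) and on the mean (1 of 100, 1677 against 12). It can also be excluded for LR12 against the peptide control at 2 h (2 of 100, 472 against 647) and 4 h (2 of 100, 217 against 334), and against vehicle at 2 h (2 of 100, 2544 against 3009), 4 h (1 of 100, 1910 against 1221) and 8 h (3 of 100, 435 against 1249). The split with 3009 genes puts Y31303 with the LR12 animals in place of Y31309, as does that with 1660, which points to a structure of the animals. For LR12 against the peptide control at 8 h chance cannot be excluded (17 of 100, 3 against 73). At 0 h it cannot be excluded against vehicle (8 of 100, 3 against 464), while for LR12 against both control arms and the peptide control the count was 0, which 100 of 100 splits reach by construction (highest others 806 and 2). The splits with 806 and 464 genes each put every high-control array on 1 side, so they follow the array batch in part. For the peptide control against vehicle chance cannot be excluded at 4 h (12 of 35, 1 against 2453), and the counts of 0 at 0, 2 and 8 h (highest others 2, 1570 and 2360) decide nothing. The highest others at 2, 4 and 8 h are the exchange of Y31303 and Y31305, which puts only high-control arrays on 1 side at 4 and 8 h, while no array of these animals was one at 2 h. For the change from 0 h chance can be excluded at 2 h (1 of 100, 466 against 94). It is left open at 4 h (3 of 100, 24 against 58) and 8 h (2 of 100, 5 against 55), where another split also called more genes.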

How the results depend on the processing

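The settings with the array batch, alone or with the animal as a block, those within low-control or high-control arrays, and the one without Y31303 and Y31305 together were chosen after the data were examined. The other settings were planned. Of 859 values of named genes, 794 kept their direction and their side of the threshold with arrays centred on their median, 775 with quantile normalization, 840 with an offset, and 816 with the array batch as a covariate. The block for the animal does not apply to the means over hours, and of the values left 754 kept both, 2 lost their call and 25 gained one. With only the arrays of the groups compared, 589 kept both, 184 lost their call and 8 gained one. High-control arrays alone kept 148 and lost the call of 164. The counts of the LR12 arm stayed within 1.5 times their value except with each probe set on its own and with the fold threshold. Where a count or direction moved, the cause was not tested, except that a fold threshold calls fewer genes by construction and more probe sets than genes are tested when each stands on its own.

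Quantile normalization gave 1, 0 and 1 genes in the vehicle arm at 2, 4 and 8 h, 253 in the peptide control arm at 8 h, 259, 142 and 0 for LR12 against the peptide control at 2, 4 and 8 h, 89 for LR12 against both control arms at 8 h, 2 for the peptide control against vehicle at 2 h and 0 for the change to 8 h. It turned 3 list results from higher to lower. These were ribosomal proteins, LR12 2 h versus 0 h (adjusted p = 4.96e-05), ribosomal proteins, LR12 versus vehicle at 2 h (0.00196) and ribosomal proteins, change from 0 h to 2 h, LR12 versus both controls (0.000549). Centred arrays gave 4 genes in the vehicle arm at 4 h, 148 and 1 for LR12 against the peptide control at 2 and 8 h, and 106 and 0 for the change to 2 and 8 h, and turned to higher the result for ribosomal proteins, LR12 versus peptide control at 8 h (adjusted p = 0.0473).

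An offset before the log gave 0 genes for LR12 against vehicle at 0 h, for LR12 against the peptide control at 8 h and for the change to 8 h. Without a filter there were 5 genes in the vehicle arm at 4 h, 2 for the peptide control against vehicle at 2 h, 172 for LR12 against both control arms at 8 h, and 0 for LR12 against the peptide control at 8 h and for the change to 8 h. The stricter filter gave 0 and 2 genes in the vehicle arm at 4 and 8 h, 0 for LR12 against vehicle at 0 h and 6 for the peptide control against vehicle at 2 h.

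The mean of a gene's probe sets gave 72 genes in the peptide control arm at 8 h, 1 for LR12 against vehicle at 0 h, 96 for LR12 against the peptide control at 4 h, 4 for the peptide control against vehicle at 8 h, and 277, 10 and 0 for the change to 2, 4 and 8 h. It reversed LAT2 in LR12 against both control arms at 4 h (0.72 to -0.10) and RPL36 there (-0.50 to 0.35) and in LR12 against the peptide control at 2 h (-0.69 to 0.026). Each probe set on its own gave 0 calls in the vehicle arm at 4 h, 949, 1237 and 275 in the peptide control arm, 9616, 11600 and 8767 in the LR12 arm, and 1 for LR12 against vehicle at 0 h. It gave 4022 and 2845 for LR12 against both control arms at 2 and 4 h, 4056 and 3216 against vehicle, 0 against the peptide control at 8 h, 6, 4 and 9 for the peptide control against vehicle, and 0 for the change to 8 h.

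Only the arrays of the groups compared gave 0 genes in the vehicle arm at 4 and 8 h, 92 and 2 in the peptide control arm at 2 and 8 h, and 0 for LR12 against vehicle at 0 h. For LR12 against the peptide control they gave 1, 34 and 0 at 2, 4 and 8 h, against vehicle 1678, 885 and 15, and against both control arms 955 and 30 at 4 and 8 h. For the peptide control against vehicle at 4 h they gave 0, and the change to 4 and 8 h 40 and 2. Moderation without trend and robustness gave 7 genes in the vehicle arm at 4 h, 178 for LR12 against both control arms at 8 h, 1064 on the mean of the hours and 0 for the change to 8 h. A threshold of 1 on the absolute log2 change left 3283, 3903 and 2809 genes in the LR12 arm, and 1385, 868, 171 and 587 for LR12 against both control arms at 2, 4 and 8 h and on the mean.

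The pairing of arrays by animal raised the counts within arms. A random block for the animal called 12, 77 and 23 genes in the vehicle arm, 1223, 2449 and 688 in the peptide control arm, and 2020, 897 and 242 for the change to 2, 4 and 8 h. Between arms the random block gave 5 for LR12 against vehicle at 0 h and 744 at 8 h, 726 and 10 for LR12 against the peptide control at 2 and 8 h, 483 for LR12 against both control arms at 8 h, and 4 for the peptide control against vehicle at 4 and 8 h. A fixed block gave 61, 178 and 22 in the vehicle arm, 1545, 3005 and 1000 in the peptide control arm, and 2613, 1535 and 908 for the change. A fixed block cannot test arms against each other at 1 hour and was not run there.

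The array batch as a covariate gave 1 and 8 genes in the vehicle arm at 2 and 4 h, 366 in the peptide control arm at 8 h, 2912, 1163 and 2938 for LR12 against both control arms at 4 h, 8 h and on the mean, 14 against the peptide control at 8 h and 2978 and 1174 against vehicle at 4 and 8 h. Counts were 16, 3 and 4 for the peptide control against vehicle, and the change to 2 and 4 h 117 and 74. With both the block and the batch, the vehicle arm gave 11, 155 and 28 genes, the peptide control arm 1499, 2360 and 1036, LR12 against the peptide control 912, 529 and 42, LR12 against both control arms 2913 and 1493 at 4 and 8 h, and LR12 against vehicle 3176 and 1494. It gave 11, 3 and 7 for the peptide control against vehicle, and the change 1019, 1313 and 74. Low-control arrays alone gave 48, 4 and 2 genes in the vehicle arm, and 0 and 1895 for LR12 against vehicle at 0 and 8 h. High-control arrays alone gave 1 and 2 in the vehicle arm at 4 and 8 h, 39 and 199 in the peptide control arm, 63 and 34 for LR12 against both control arms, 15 and 1 against the peptide control, 61 and 37 against vehicle, and 2 for the peptide control against vehicle at 8 h. Comparisons whose groups kept fewer than 2 arrays of a set could not be run there.

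Leaving out each animal in turn gave 0 to 3, 0 to 6 and 0 to 7 genes in the vehicle arm, 18 to 880, 1 to 1946 and 0 to 558 in the peptide control arm, and 4195 to 4833, 5060 to 5703 and 3465 to 4291 in the LR12 arm. For LR12 against both control arms the ranges were 0 to 1 at 0 h, 1679 to 3474, 841 to 2904 and 65 to 1887 at 2, 4 and 8 h, and 226 to 3669 on the mean. Against the peptide control they were 0 to 1, 113 to 1390, 14 to 426 and 0 to 63, and against vehicle 0 to 5, 1392 to 3522, 709 to 3718 and 53 to 2668. The peptide control against vehicle ranged over 0 to 2, 0 to 638, 0 to 1029 and 0 to 221, and the change over 41 to 1171, 1 to 649 and 0 to 125. The number of list calls ranged from 212 to 283 over 570 tests, where it was 236 to 278 with all animals. Single animals turned 4 lists over. The result for mature neutrophil markers, peptide control versus vehicle at 0 h, did so without Y31302 (adjusted p = 0.839, with 0.000233 as the lowest over all animals), and that for NF-kB feedback and early response, vehicle 2 h versus 0 h, without Y31303 (0.75, lowest 0.000421). The others were neutrophil granule genes, vehicle 8 h versus 0 h, without Y31303 (0.0471, highest 0.754), and interferon response, peptide control versus vehicle at 2 h, without Y31307 (0.0253, highest 0.921).

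Without Y31303 and Y31305 together, 0 genes were called in the vehicle arm at 4 h and 1339, 2814 and 1165 in the peptide control arm. The peptide control against vehicle then gave 1, 1515, 2265 and 1577 genes at 0, 2, 4 and 8 h, LR12 against the peptide control 235, 57 and 5, LR12 against vehicle 3958 and 3027 at 4 and 8 h, LR12 against both control arms 1284 at 8 h and 3229 on the mean, and the change 791, 388 and 69. These animals were picked from their values, so these counts are no independent evidence. In the vehicle arm, NF-kB feedback and early response at 2 h (adjusted p = 0.692) and neutrophil granule genes at 8 h (0.00845) turned to lower.

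Of the 382 list calls, 20 held with an estimated correlation, and fry gave 190. Quantile normalization gave 369, centring 387, the batch 383 and the block 380. Signal over background limits what dim probe sets show. Human probes were read with macaque RNA, and no detection calls were at hand, so a gene that was not called or not kept, such as IL10, is not shown to be absent.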

Other observations

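GJB2 and AHSP, picked after their values were seen, had different means between the arms at 0 h, uncalled, and at later hours. GJB2 lay in the peptide control arm at 2.31 ± 0.74, 4.74 ± 0.83, 2.30 ± 1.51 and 2.70 ± 1.35 (mean ± SD, n = 4) at 0, 2, 4 and 8 h. It lay in the LR12 arm at 5.47 ± 1.59, 7.87 ± 0.93, 5.88 ± 1.22 and 6.38 ± 1.30 (n = 6), and in the vehicle arm at 5.54 ± 0.12, 6.56 ± 0.93, 5.74 ± 0.93 and 6.21 ± 0.99 (n = 4). Between LR12 and the peptide control it was called at 2, 4 and 8 h but not at 0 h (adjusted p = 0.465), and between the peptide control and vehicle at no hour. At 0 h 0 of 18 erythroid markers were called against both control arms, and the call of the list was lost with an estimated correlation. AHSP was 6.70 ± 0.57 at 0 h and 5.26 ± 0.35 at 8 h in LR12 animals, 7.54 ± 0.57 and 6.83 ± 0.60 in peptide control animals, and 7.69 ± 0.42 and 7.43 ± 0.63 in vehicle animals.

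EPDR1 fell in all arms. It averaged 4.44 in vehicle, 4.03 in peptide control and 4.71 in LR12 animals at 0 h, and 0.59, -0.10 and -0.18 at 8 h. At 0 h these levels lay near the middle of the array, and at 8 h under its 20th percentile.

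From the known action of LR12 it was asked whether LR12 lowers the response seen in the peptide control arm, a test chosen after the results were seen. Over the 528 genes called in the peptide control arm at 2 h, 523 moved in the same direction in the LR12 arm, and 362 changed more there. The median ratio of the change in the LR12 arm to that in the peptide control arm was 1.19, and it ran from 0.983 without Y31305 to 1.32 without another animal. A lower response in LR12 animals was not seen over these genes, but it cannot be told apart from an equal or a larger one, since the sign of the difference rests on Y31305. The genes were picked in the peptide control arm, which enlarges their change there. IL1B and TNF showed no call between these arms.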
